A study of Mus musculus with 2 samples.

How the data were processed

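The samples were 2 libraries of the Chromium single-cell ATAC kit (version v1), from pituitaries of 2 adult male C57BL/6 mice, with 6000 nuclei aimed for in each. Per the submitters' processing notes, the authors used Cell Ranger ATAC (version not given) with the genome build mm10. The deposited matrix gives whole-number counts per motif and nucleus, as the authors' pipeline made them, not divided by depth; a peak with several motifs counts for each of them. The peak calling, nucleus calling and motif scanning settings are not given in the sources used here. The deposited peak list and its annotation (promoter, distal or intergenic, nearest gene and distance) hold positions and no measured values, and the counts per peak and nucleus were not used here. Libraries are numbered by the suffix of the barcodes (1 or 2); the labels do not state which gland carries which suffix. Of the barcode sequences, 101 occurred in both libraries, and no pair of nuclei had identical counts.

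Choices named here as design were made before the data were examined. Barcodes with a total under 1/10 of the median (18442 motif counts) were left out. This kept 5090 of 7123 barcodes in library 1 (71.5%) and 5667 of 7727 in library 2 (73.3%). Counts were divided by the total of the nucleus, scaled to the median total, log-transformed as log(1+x), centred and scaled per motif. Clusters came from 15 principal components, 15 neighbours and Leiden clustering at resolution 0.5 (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, umap-learn 0.5.12, Python 3.11.15). Doublets were not called. An alternative leaves out only the deepest nuclei, those over the 97.5th percentile of totals (933549 counts), and cannot stand in for doublet calling. The 78 motifs that name a marker factor were left out of the clustering, which used the other 501. Of 79 marker names, 5 were not in the matrix (FOXL2, NKX2-1, NR5A1, SOX18 and TAL1::GATA1), and 74 motifs were tested. Motifs share peaks and are not independent: only 545 of the 579 count vectors were distinct, and 8 tested markers had the same counts as a clustering motif. Shares of nuclei have Wilson 95% intervals, which cover counting error only.

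For the motif comparison, counts were summed per library and cluster over the 7 clusters with at least 20 nuclei in each library, which gave 14 sums of between 14498979 and 748527018 counts. The test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM composition factors, library as a block, 6 residual degrees of freedom and Benjamini-Hochberg adjustment over all 579 motifs at a threshold of 0.05. First any difference between clusters was tested, then each cluster against the mean of the others. The log2 ratios printed are means over the 2 libraries. A motif is called higher or lower when it passes the threshold and has the same sign in both libraries. With the default trended dispersions of edgeR, the deviance of 89 motifs was numerically wrong, because dispersions under 1e-04 are handled by an approximation that fails for sums as large as these, and 44 motifs had a negative F in some cluster. Dispersions were therefore floored at 0.000101, which applied to 92 motifs. This was done after the first results were seen, and the deviances were then checked against the exact formula. Simulated counts were tested the same way: with 200 of 579 motifs changed in cluster 1, the test recovered 94% of those changed 1.05-fold and 100% of those changed 1.5-fold, and 1.99% of its calls were false. The simulated motifs were independent, with a single dispersion and no library effect, and as many were raised as lowered. Real motifs share peaks and most differ between clusters, so these rates need not hold for them. DESeq2 1.42.0 was run as an alternative.

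Peaks were counted per annotated gene. Of 16696 gene symbols, 15566 (93.2%) matched the gene table of the same build (GRCm38.p6). The median number of peaks over each of 14 gene lists was compared with 10000 random lists of the same size from the 15561 genes with an annotated peak, matched on deciles of gene length, by a 2-sided permutation test with Benjamini-Hochberg adjustment over the lists. The unadjusted p of the transcription factors, 0.0002, is the smallest these random lists can give. This p describes a list among genes, not animals. A first run drew from all protein-coding genes, and the design's background replaced it; the former is kept as an alternative. On simulated lists of 15 genes, 2% of 100 unchanged lists and 97% of lists raised by 4 peaks per gene came under 0.05.

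The gene lists were hormones, receptors for hypothalamic and feedback signals, pituitary lineage transcription factors, secretory granule and exocytosis, stem and folliculostellate, endothelial, myeloid, mesenchymal and pericyte, posterior lobe pituicyte, hepatocyte, striated muscle, keratinocyte, spermatid and housekeeping. The 10 motif classes were POU1F1 lineage, corticotrope or melanotrope, gonadotrope, stem or folliculostellate, myeloid, endothelial, mesenchymal or pericyte, lymphoid, erythroid and posterior lobe pituicyte. The rule for named items took, for each cluster, the 3 marker motifs with the highest fitted ratio among those higher in both libraries, and, as description, the 3 highest clustering motifs. It took every gene of the hormone and lineage transcription factor lists, the 3 genes with the most peaks of each other list and the 10 genes with the most peaks in the genome. Some items that this rule takes are not reported here by name, but stay in the counts and medians of their lists.

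The libraries were compared by the log2 ratio of each motif's share of all counts, with a bootstrap interval of 2000 draws over motifs (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Alternatives changed the clustering settings, the depth filter, the normalisation, the count filter, the test, the library block, the way peaks are counted and the gene background. A planned search for consensus sites in peaks was not run, since no genome sequence was at hand, and neither was a covariate for the GC content or promoter share of motifs, which the deposited data do not give. The marker test without a library leaves no residual degrees of freedom.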

Results

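Open chromatin was profiled in single nuclei of the pituitary, the hormone gland below the brain, from 2 adult male C57BL/6 mice. The assay, single-cell ATAC-seq, uses a transposase that cuts accessible DNA. All samples formed 1 group, adult male pituitary, with 2 replicate libraries from separately processed glands. Library 1 held 7123 barcodes with 1931176458 motif counts in all and a median of 192921 per barcode. Library 2 held 7727 barcodes with 1649777792 motif counts in all and a median of 178458 per barcode. The counts were given for 579 transcription factor motifs. A single list of 70133 accessible regions, called peaks, covered both libraries, so values taken from peaks have no replicates.

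Transcription factor genes of the pituitary lineages and genes of secretory granules carried more accessible regions than random lists of genes of similar length. Only genes with an annotated peak were compared. Transcription factors of the pituitary lineages had a median of 7 peaks per gene, against 2 in random lists, of which the central 95% lay between 1 and 3. Genes of secretory granules and exocytosis, which store and release the hormones, had a median of 9.5 peaks, against 3 in random lists (2 to 5.5). Hormone genes had a median of 5.5 peaks, against 1.5 (1 to 4), over the 6 of 7 with a peak. Receptors for hypothalamic and feedback signals also had a median of 5.5 peaks, against 2.5 (1 to 4.5). The comparison asks whether accessible regions gather at genes of pituitary function. The 2-sided permutation p, adjusted over 14 lists, was 0.00280 for the transcription factors and for the granule genes, and 0.0343 for the hormones and for the receptors. The last 2 lists missed the threshold under several alternatives: with genes without a peak counted as 0, the hormone genes had a median of 4 against 1 (0.0658).

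Of the hormone genes, Prl, which encodes prolactin, had 9 peaks, with a promoter peak on chromosome 13 from 27056240 to 27058438 (mm10). Pomc, the precursor gene of corticotropin and melanotropin, had 7 peaks, with a promoter peak of 791 bases on chromosome 12 from 3954488 to 3955278. Gh, which encodes growth hormone, had 4 peaks, and its promoter peak of 5516 bases on chromosome 11, from 106297576 to 106303091, covered most of the gene. Cga, which encodes the alpha subunit shared by thyrotropin and the gonadotropins, had 4 peaks, with a promoter peak of 691 bases on chromosome 4 from 34893264 to 34893954. Tshb, the thyrotropin beta subunit gene, had 7 peaks, all annotated as distal, the nearest 3.93 kb from the start site. Both gonadotropin beta subunit genes stood apart: Fshb had 1 peak, 91.0 kb away, and Lhb had no annotated peak and was not in the tested list of 6 genes. Distal peaks count for the nearest gene, so a low count need not mean that no accessible region lies nearby. Close to Gh, for example, the peak from 106309914 to 106310708 was annotated to Cd79b.

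**Figure D1:**
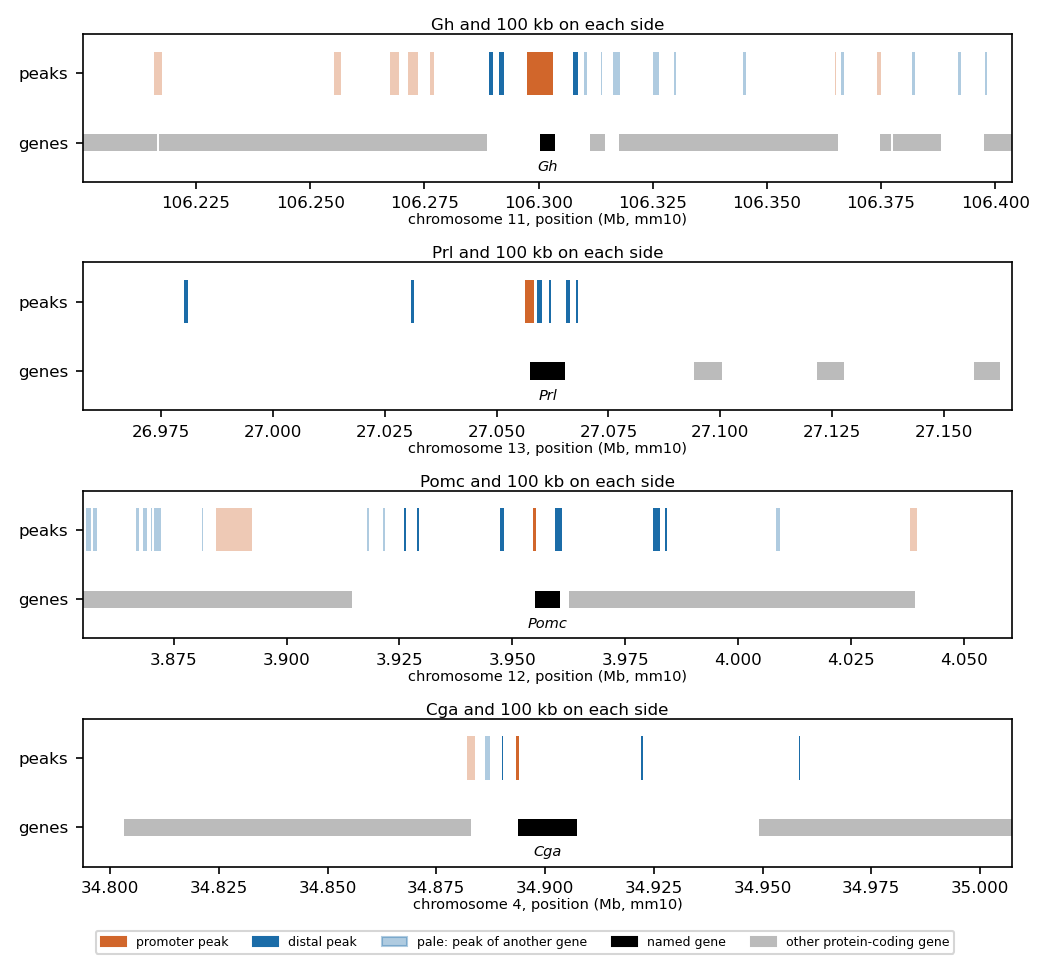
Peaks (upper track) and protein-coding genes (lower track) at Gh, Prl, Pomc and Cga with 100 kb on each side; the horizontal axis is the position in Mb (mm10), pale peaks are annotated to another gene, and the narrowest peaks are drawn at a minimum width. The promoter peak of Gh is 5516 bases wide, that of Pomc 791 and that of Cga 691.

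All 24 lineage transcription factor genes had a peak, and 19 had a promoter peak. Insm1, a factor of endocrine cells, had 22 peaks. Pou1f1, which specifies somatotropes, lactotropes and thyrotropes, had 21, as did Foxo1. Pitx1 had 15 peaks, Six3 14, Eya1 12 and Lhx3 10. Tbx19, which drives Pomc in corticotropes, had 13 peaks, all distal. The gonadotrope factor Nr5a1 had 7 peaks, all distal, and Pax7, the factor of melanotropes, had 5 distal peaks. Egr1 had 8 peaks, Neurod4 7, Isl1 6, Gata2 and Lhx4 4 each, Neurod1 3 and Foxl2 2. Hesx1, Six6 and Otx2 had 1 peak each, and Otx2 also lacked a promoter peak. The promoter peak of Egr1 spanned 12337 bases (chromosome 18, 34858994 to 34871330).

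Among the receptors, the estrogen receptor gene Esr1 and the thyroid hormone receptor gene Thrb had 23 peaks each, and the ghrelin receptor gene Ghsr had 13. Among the granule genes, Ptprn2 had 39 peaks, Pam 28 and Syt1 18. Lists for other cells of the gland had medians inside the range of random lists, 2.5 peaks for stem and folliculostellate genes (Sox2 11, Krt8 5, Krt18 4), 3 for endothelial genes (Pecam1 8, Emcn 6, Kdr 5) and 2 for myeloid genes (Irf8 8, Aif1 2, Cd68 2). Mesenchymal and pericyte genes had a median of 3 (Col1a2 22, Foxc1 8, Pdgfra 6), and pituicyte genes of the posterior lobe 3.5 (Lhx2 8, Col25a1 4, Rax 4). Over their genes with a peak, lists of other tissues had medians of 2 for hepatocyte genes (Apoa1 10, Apob 10, Ttr 6), 2 for striated muscle (Ryr2 10, Ttn 7, Myl7 5), 1.5 for keratinocytes (Tgm3 7, Krt1 2, Krt10 1) and 1.5 for spermatids (Tnp1 8, Odf1 5, Oaz3 2). Housekeeping genes had a median of 2 (Ywhaz 16, Eef1a1 6). Each of these 10 lists had an adjusted permutation p of 1. Only 7 of 15 hepatocyte, 4 of 13 keratinocyte and 6 of 13 spermatid genes had a peak; with the others counted as 0 the medians of these 3 lists were 0, and that of the stem and folliculostellate genes, 10 of 15 with a peak, was 1. With promoter peaks alone the median was 1 for the 4 raised lists and for random lists alike, so that this measure hardly tests them. The hormones and receptors missed the threshold with the mean in place of the median or without matching on gene length, though they stayed above the mean of random lists, by 2.70 peaks in both for the hormones (3.65 in the main comparison) and by 3.76 and 2.99 for the receptors (2.99). With matching on the distance to neighbouring genes as well, both missed it with differences of 3.11 and 2.11, and within 50 kb of the start site the receptors missed it with 1.32. Over the alternatives other than promoter peaks alone, the adjusted permutation p ran from 0.0187 to 0.459 for the hormones and from 0.0233 to 0.413 for the receptors. The transcription factors and granule genes passed the threshold in each. Within 50 kb of the start site, though, the excess of the granule genes over the mean of random lists fell from 6.29 to 2.96 peaks.

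**Figure D2:**
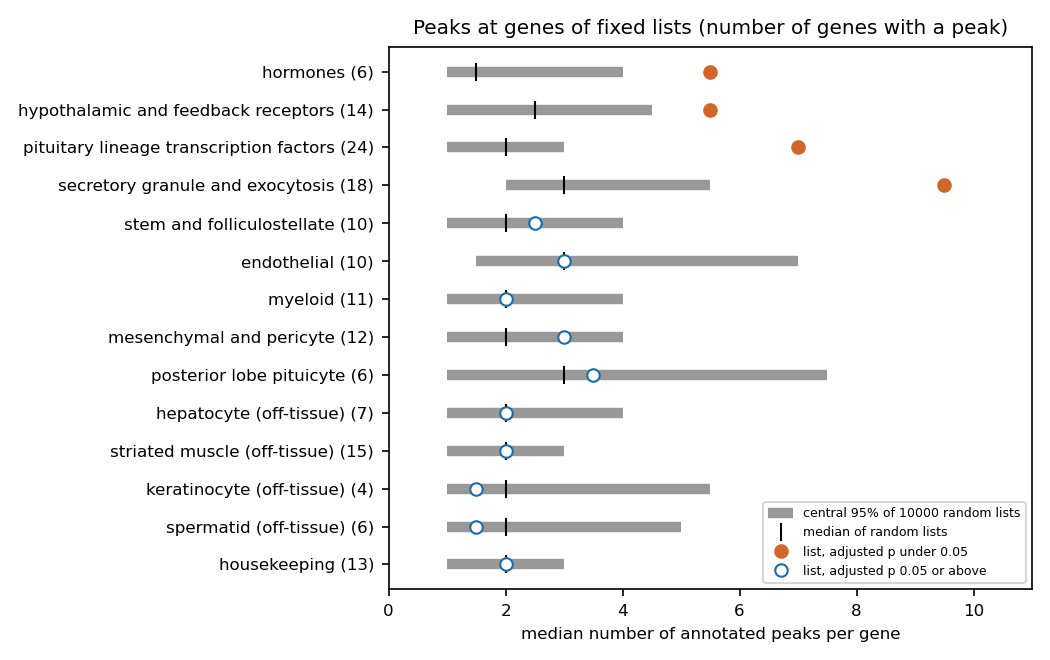
Median number of annotated peaks per gene (horizontal axis) for each of 14 gene lists, with the number of genes in brackets; points are the lists, black ticks the medians and grey bars the central 95% of 10000 random lists matched on gene length. The lineage transcription factors (7) and granule genes (9.5) lie farthest beyond their bars, which end at 3 and 5.5.

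The gene with the most peaks in the genome was Auts2, with 81 peaks over a gene of 1106 kb. Next came Agap1 with 69, Zbtb20 with 60, Pde4d with 54, Maml3 with 51, Kcnma1 with 49 and Nav2 with 48. Arid1b, Frmd5 and Prkca had 46 each. The median over genes with a peak was 2. The widest peak, of 21418 bases, lay at Gnas on chromosome 2 from 174326808 to 174348225, the gene of the stimulatory G protein alpha subunit. The next widest, of 15317 bases, lay at Jund, which encodes an AP-1 factor, on chromosome 8 from 70696396 to 70711712.

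Accessible regions lay mostly away from promoters. Of 71424 peak annotations, 20.2% were promoter (Wilson 95% interval 19.9 to 20.5), 73.5% distal (73.2 to 73.8) and 6.30% intergenic (6.12 to 6.48). Promoter peaks were the wider ones, with a median of 1474.5 bases against 501 for distal and 454 for intergenic peaks. Of 21883 protein-coding genes, 12725 (58.2%) had a promoter peak and 15439 (70.6%) had any peak. The median distance of a distal peak from the start site of its gene was 26.7 kb, and some distal peaks lie inside their gene, as at Prl. Among peaks at least 500 bases wide the promoter share was 32.5%, over 1.5 times as high, so the split depends on how many narrow peaks are counted. The intervals cover counting error only.

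The nuclei fell into 8 clusters by motif counts, 7 of them large enough to compare, and cluster 5 took very different shares of the libraries. Cluster 5, with the highest shares of AP-1 motifs, held 24.6% of library 1 (Wilson 95% interval 23.5 to 25.8) and 2.74% of library 2 (2.34 to 3.19), a 9.01-fold difference. Cluster 4 held 8.33% of library 1 (7.60 to 9.12) and 17.6% of library 2 (16.6 to 18.6). Cluster 7, with high shares of ETS motifs, held 1.39% (1.11 to 1.76) and 2.65% (2.26 to 3.10). The comparison asks which kinds of nuclei the gland holds and how evenly both glands contain them.

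As means over both libraries, cluster 1 held 25.6% ± 5.28 (SD, n = 2) of the nuclei, cluster 2 19.9% ± 5.92, cluster 3 15.3% ± 2.61, cluster 4 13.0% ± 6.55, cluster 5 13.7% ± 15.5, cluster 6 10.5% ± 0.520 and cluster 7 2.02% ± 0.885. Cluster 6 had shallow nuclei, with a median of 29806 motif counts against 289235 over all nuclei kept. Nuclei of cluster 5 were deep in library 1, with a median of 585000 against 323119.5 over its kept nuclei, but less so in library 2, with 306906 against 267742. The remaining cluster held 11 nuclei. No cluster was given a cell type name, since motif counts alone could not be matched to marker genes. In none was more than 1 of its 10 highest motifs a cell type marker. That count says little, since only 74 of 579 motifs are markers and motifs with the same counts as a marker were not counted. Each library is a single sample, so the difference in shares has no test. When the 9694 nuclei with at least 46105 counts were thinned to that total and clustered anew, the largest fold was 3.04, in a cluster of 3107 nuclei (49.6% of library 1 and 16.3% of library 2). At a finer clustering resolution of 1.0 there were 11 clusters. Clusters with an over 3-fold difference between libraries numbered 1 here, and between 1 and 3 over the alternatives. Many nuclei change cluster with the settings: the adjusted Rand index to the clusters used here, which is 1 for identical clusters, ran from 0.404 to 0.697 over the alternatives.

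**Figure D3:**
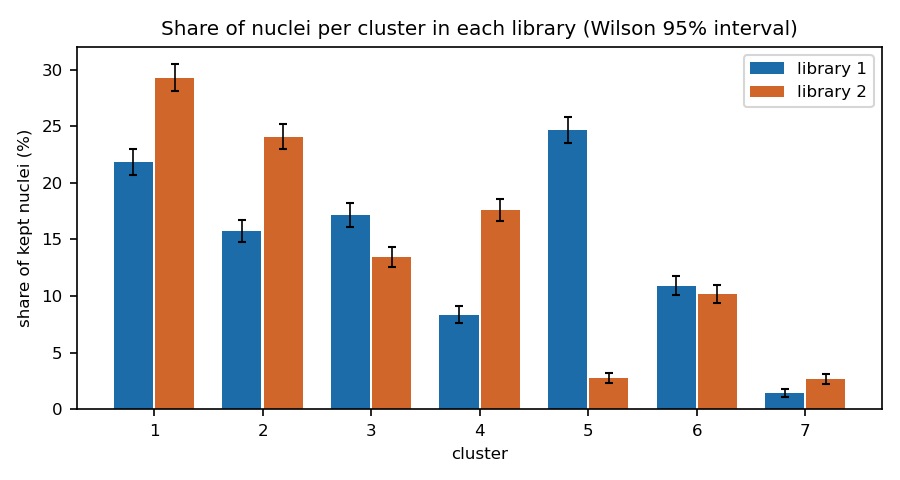
Share of kept nuclei in percent (vertical axis) in each of 7 clusters (horizontal axis); bars are single libraries and error bars Wilson 95% intervals. Cluster 5 holds 24.6% of library 1 and 2.74% of library 2.

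Motifs of blood vessel and immune cell factors were high in cluster 7. Of 7 motifs listed for endothelial factors, 6 were higher there, among them the ETS motif ELK3 with a log2 ratio to the mean of the other clusters of 0.50 ± 0.0047 (SD, n = 2 libraries). All 8 myeloid motifs were higher, among them SPI1 (PU.1, which specifies macrophages) at 0.52 ± 0.04; without composition factors 7 of them were. Other classes were high too: 4 of 5 gonadotrope motifs, with a median of 0.12, and 4 of 6 lymphoid motifs, with a median of 0.21. Without composition factors the counts were the same, with medians of 0.06 and 0.14. The endothelial, myeloid and lymphoid lists all hold ETS motifs, and ETS1 is in both the endothelial and the lymphoid list. RUNX motifs are in both the myeloid and the lymphoid list. The counts of these classes thus overlap and do not count as separate signals. The gonadotrope factors NR5A1 and FOXL2 had no motif of their own in the matrix. The highest listed motif of cluster 7 was PAX7, a factor of melanotropes, at 0.75 ± 0.11. Its class went mostly the other way: of 11 corticotrope or melanotrope motifs 4 were higher and 6 lower, with a median of -0.06. Without composition factors 3 were higher and 7 lower. The lower ones include NEUROD1, NEUROD2 and EOMES. Of 74 marker motifs, 66 differed between clusters by the edgeR quasi-likelihood test at an adjusted p under 0.05, both adjusted over all 579 motifs and adjusted over the list alone. Of all 579 motifs 542 passed, so the marker motifs do not stand out in this count. The comparison asks which cell type factors' motifs are unequally accessible among nuclei. Related factors share a motif, so each name stands for a family, and FEV had the same counts as ELK3. Both also had the same counts as the clustering motifs ERF, ETV1, ETV4, ETV5 and ELK1, as LHX9 had those of ISX and Prrx2. Their values thus restate motifs that helped to form the clusters. The same holds for CEBPB and CEBPD among the myeloid motifs and GATA3 among the gonadotrope motifs. It also holds for TBX15 and TBX1 among the corticotrope or melanotrope motifs. With near copies of markers left out, the nuclei formed other clusters (adjusted Rand index 0.497). There 68 of the 74 motifs passed, but so did 545 of all 579, so this does not remove the overlap.

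Other motifs of cluster 7, chosen here after their values were seen, included the interferon factor motif IRF8 at 0.47 ± 0.04 and EGR1 at 0.35 ± 0.02, both higher. The neuroendocrine motifs NEUROD2 and NEUROD1 were lower there, at -0.29 ± 0.04 and -0.27 ± 0.09, as were EOMES at -0.32 ± 0.02 and Twist2 at -0.33 ± 0.08. The endothelial motif that was lower was Sox17, at -0.08 ± 0.03. In edgeR the adjusted p was 1.3e-09 for PAX7, 1.1e-12 for SPI1 and 1.8e-13 for ELK3. That of ELK3 is no separate test, since clustering motifs had the same counts. SPI1 is an ETS factor too, and the ETS motif EHF, at 0.66 in cluster 7, helped to form the clusters. The result for SPI1 is thus not independent of the clustering either. In all, 36 marker motifs were higher and 25 lower in cluster 7, and 27 and 37 without composition factors.

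Cluster 5 had the highest NFE2 motif of the clusters, at 0.35 ± 0.10, with NEUROD2 at 0.10 ± 0.00097 and NEUROD1 at 0.07 ± 0.0030, though without cluster 7 the fitted ratios fell to 0.07 and 0.03, and NEUROD1 missed the threshold (adjusted p 0.0807 in edgeR). The NFE2 site resembles that of AP-1, and the AP-1 motifs FOSB::JUNB and FOSL1::JUND, which helped to form the clusters (FOSL2::JUND has the same counts as FOSB::JUNB), stood at 0.33 ± 0.05 and 0.32 ± 0.06. All 8 myeloid motifs were lower in cluster 5, with a median of -0.11, and 7 were without composition factors. The 5 gonadotrope motifs were lower too, but only 2 were without these factors or without cluster 7. In total 5 marker motifs were higher and 32 lower, and 17 and 15 without composition factors. Without cluster 7 they numbered 9 and 15, with 5 of the myeloid motifs lower. None of the 7 endothelial motifs was higher or lower in the main comparison, but 6 were higher without cluster 7, and 5 without composition factors.

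Clusters 1 and 4 were low in ETS motifs. In each, 6 of the 7 endothelial motifs were lower, with a median log2 ratio of -0.21 in both; without cluster 7 it was -0.14 in cluster 1 and -0.15 in cluster 4. Cluster 1 was led by NFE2 at 0.23 ± 0.0099, the T-box motif EOMES at 0.14 ± 0.0048 and the mesenchymal motif Twist2 at 0.13 ± 0.05. Cluster 4 was led by the homeodomain motifs LHX2 at 0.14 ± 0.03 and LHX9 at 0.13 ± 0.0070 and the Wnt pathway motif LEF1 at 0.13 ± 0.02. Of 6 pituicyte motifs, 4 were higher in cluster 4, and 3 without composition factors. Marker motifs numbered 23 higher and 19 lower in cluster 1, and 37 and 14 without composition factors. In cluster 4 they numbered 21 higher and 20 lower, and 16 and 24 without these factors. These ratios depend on cluster 7 being among the others: without it the fitted ratios were 0.09 for EOMES and 0.07 for Twist2 in cluster 1 and 0.07 for LEF1 in cluster 4, all still past the threshold. Marker motifs then numbered 19 higher and 15 lower in cluster 1, and 10 and 11 in cluster 4.

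Endothelial motifs were also high in cluster 2, where 5 of the 7 were higher, with a median of 0.07; without cluster 7 these were 6 and 0.14. Its marker motifs were led by EGR1 at 0.10 ± 0.02, PAX7 at 0.08 ± 0.03 and PAX5 at 0.08 ± 0.05, with 20 higher and 8 lower. Without cluster 7 the fitted ratios were 0.15, 0.21 and 0.15, and 27 marker motifs were higher and 18 lower, the most of any cluster. PAX7 missed the threshold in cluster 2 without cluster 6, where its fitted ratio fell from 0.09 to 0.04 (adjusted p 0.189 in edgeR). It also missed it without cluster 5, where the ratio was still 0.08 (0.0621). Cluster 3 had 2 higher motifs, LHX9 at 0.05 ± 0.0096 and FOXC2 at 0.04 ± 0.0044, and 16 lower ones, or 10 lower ones without composition factors. Cluster 6, the shallow one, had no higher and 13 lower marker motifs, against 11 and 8 without composition factors. Most of the lower motifs of both depend on cluster 7: without it cluster 3 had 7 higher and 4 lower ones and cluster 6 none either way. The motifs that formed the clusters are given as description: ZBTB7B was highest in clusters 4 (1.20 ± 0.06) and 3 (0.87 ± 0.02), and so were SOX4 (0.75 ± 0.07 and 0.52 ± 0.02) and HIF1A (0.59 ± 0.05 and 0.41 ± 0.0022). In cluster 1 the leading ones were NR3C1, JDP2 and FOSL1::JUND (each 0.19). In cluster 2 they were ZBED1 (0.33 ± 0.09), Hes2 (0.19 ± 0.16) and HOXC13 (0.17 ± 0.20), and in cluster 7 MYBL1 (0.82 ± 0.07), CENPB (0.75 ± 0.01) and EHF (0.66 ± 0.03). In cluster 6 ZBED1 (0.15 ± 0.41) and PROX1 (0.17 ± 0.35) differed in sign between the libraries, and Rarg(var.2) stood at 0.09 ± 0.05.

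The motifs listed for the POU1F1 lineage, that of somatotropes, lactotropes and thyrotropes, went both ways in cluster 7. There the 9 motifs lay between -0.11 and 0.12, with 3 higher and 3 lower, and 2 higher and 5 lower without composition factors. POU1F1 itself was lower in cluster 7, at -0.11 ± 0.03. The marker motifs had a median range over clusters of 0.15 on the log2 scale, and the largest range was 0.89 for PAX7. The edgeR p-values rest on how much the differences between clusters vary between the 2 libraries, since the block removes each library's own level. They take the clusters as given, though these came from the counts of the same nuclei. Without cluster 7, shallow cluster 6 and cluster 5, which is mostly library 1, 36 of the 74 motifs passed. That fit has fewer sums, so a loss of power was not separated from what these clusters add.

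**Figure D4:**
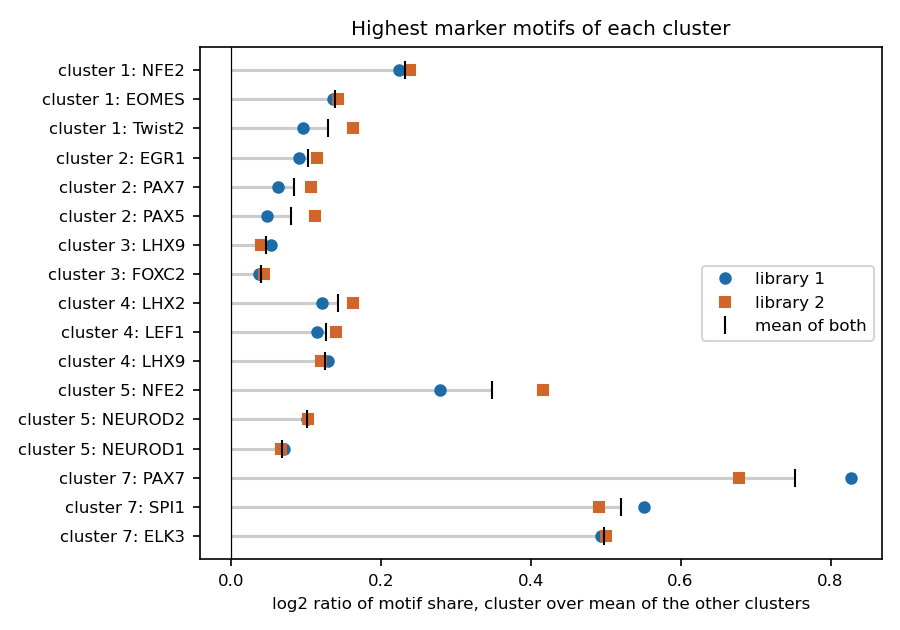
Log2 ratio of the motif share in a cluster to the mean of the other clusters (horizontal axis) for the highest marker motifs of each cluster; circles are library 1, squares library 2 and ticks their mean. PAX7, SPI1 and ELK3 in cluster 7 have means of 0.75, 0.52 and 0.50, and cluster 6 has no higher marker motif.

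Over all nuclei, the 3 AP-1 motifs that led cluster 5 took a larger share in library 1 (median log2 ratio 0.125), and ZBTB7B and SOX4 in library 2. The AP-1 motifs as a whole were not compared. The AP-1 motif FOSL1::JUND had a log2 ratio of library 1 to library 2 of 0.13, NFE2 of 0.15 and ZBED1 of 0.19, the highest. At the other end lay ZBTB7B at -0.33, SOX4 at -0.20, HIF1A at -0.15 and the glucocorticoid receptor motif NR3C1 at -0.14. These motifs were chosen after their values were seen. The median absolute log2 ratio over 579 motifs was 0.0209 (bootstrap 95% interval over motifs 0.0192 to 0.0224), and 95.3% of motifs lay within 0.1 either way. This measure is small between clusters as well: within a library, clusters 1 to 6 lay 0.0148 to 0.0647 from all kept nuclei, so the value does not show that the glands are alike. Of the 27 motifs beyond 0.1, 16 were higher in library 1 and 11 lower. Motifs are not independent replicates, and with 1 library per gland the ratios have no test.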

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

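Both results come from barcodes left out of the motif test between clusters; the comparison of the libraries over all nuclei included them. The test of the motif profile of shallow barcodes was chosen after that result was seen. The design has 1 group, so no biological explanation was tested.

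A total of 4093 barcodes lay under the depth floor yet held motif counts, with a median total of 6121 and a lowest total of 2117. All are in the barcode list that the authors deposited, so some counts had to be there. A peak counts for each of its motifs, so these totals do not give the number of fragments behind them. They made up 0.785% of the counts of library 1 and 0.938% of those of library 2. Their motif profile lay close to that of all kept nuclei: the median absolute log2 ratio was 0.0170 in library 1 and 0.0156 in library 2. Shallow cluster 6 had 0.0148 and 0.0162. Whether these barcodes hold nuclei at all was not tested. If they do, nuclei of a single cluster and a mixture of all cannot be told apart. Their ratio lay above that of the nearest cluster in 1 library and below it in the other.

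The 11 nuclei of cluster 8, too few to compare, had a share of CENPB motif counts 113-fold that of all kept nuclei. CENPB binds centromeric repeats. In 1 barcode of library 1 the motif took 6.82% of all counts (2780 of 40753). Without this barcode the fold was 1.97 (Poisson 95% interval 1.45 to 2.63, from 46 counts in 10 nuclei). This single barcode, with 2780 CENPB counts against 46 in the other 10 nuclei, therefore carried most of the fold. The interval reaches from under 1.5, the bound set before the test, to above it, so a small excess in the other nuclei stays open. The interval covers counting error only, and the nuclei differ: the median share of the 11 was 0.00386%, against 0.00399% of the counts of all kept nuclei, and the second highest barcode had 0.0417%.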

How the results depend on the processing

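Choices added after the data were seen were the removal of near copies of markers, thinning, the removal of clusters, matching on neighbour distance, the background of all protein-coding genes, the agreement among kept nuclei and the edgeR fit without a dispersion floor. The number of clusters stayed within 1.5 times 7 except at Leiden resolution 1.0, which gave 11, and ran from 7 to 8 without 1 replicate. The nuclei in them were less stable: the adjusted Rand index to the main clusters ran from 0.404 with thinned nuclei to 0.697 without the deepest nuclei. Marker motifs past the threshold numbered 66, and between 47 and 68 under 14 alternatives, among them DESeq2 (65), no library block (60), resolution 0.25 (51), no cluster 7 (47) and the faulty default dispersions (58). Without clusters 5, 6 and 7 there were 36, in a comparison of fewer clusters. Of 96 values of named marker motifs, 93 kept their direction and side of the threshold, and 3 kept the direction but missed the threshold in edgeR. PAX7 in cluster 2 missed it without cluster 6 (adjusted p 0.189, fitted ratio 0.04 against 0.09) and without cluster 5 (0.0621, ratio 0.08). NEUROD1 in cluster 5 missed it without cluster 7 (0.0807, ratio 0.03 against 0.07). Without cluster 7 sizes changed, from 0.09 to 0.21 for PAX7 in cluster 2 and from 0.13 to 0.07 for Twist2 in cluster 1. The difference between libraries was 0.0187 with thinned nuclei and 0.0199 to 0.0208 otherwise. The promoter share was 18.8% with each peak counted as 1, 17.3% without peaks of several annotations, 32.5% for peaks of at least 500 bases and 19.9% without sex chromosomes.

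Gene lists past the threshold numbered 4, and 2 with promoter peaks only, with the mean, without length matching and with matching on neighbour distance as well. With promoter peaks only the adjusted p was 1 for the hormones, receptors, transcription factors and granule genes, whose medians then equal those of random lists at 1, so this alternative hardly tests them. The endothelial list then passed with fewer promoter peaks than random lists (0.0210), and the mesenchymal and pericyte list (0.0210) reversed its direction, with 4 of 12 genes having a promoter peak. The hormones, 3.65 peaks above the mean of random lists in the main comparison, missed the threshold with the mean (0.258, 2.70 above), without length matching (0.459, 2.70), with neighbour matching (0.177, 3.11) and against all protein-coding genes (0.0658, 2.86). The receptors, 2.99 above, missed it within 50 kb of the start site (0.413, 1.32), with the mean (0.0849, 3.76), without length matching (0.0905, 2.99) and with neighbour matching (0.348, 2.11). Apart from promoter peaks only, the cause of these changes was not tested. The search for consensus sites with its alternatives and the GC or promoter covariate were not run, and the marker test without a library could not be fitted with residual degrees of freedom. Shallow nuclei limit what cluster 6 can show.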

Other observations

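Gene families and lists in this part, and the tests of the AP-1 motifs and of the animals, were chosen after the data were seen. Large sensory gene families had few accessible promoters: 7 of 1110 olfactory receptor genes had a promoter peak (0.631%, Wilson 95% interval 0.306 to 1.30), as did 1 of 353 vomeronasal receptor genes (0.283%), against 58.2% of all protein-coding genes. Of the Hox genes, which pattern the trunk, 2 of 39 had a promoter peak (5.13%, 1.42 to 16.9). Of the ribosomal protein genes 74 of 77 had one (96.1%, 89.2 to 98.7), with a median of 2 peaks against 1 in random lists (permutation p adjusted over 11 families, 0.00440). For families, random lists came from all protein-coding genes, with no peak counted as 0; genes with a peak have a median of 2 as well. Of the cadherin and protocadherin genes 73.9% had a promoter peak, with a median of 1 peak per gene against 2 in random lists (adjusted p 0.0429). The other 9 families did not pass the threshold (adjusted p 0.318 to 1). Among them were the olfactory and vomeronasal receptors, the Hox, Fox and Sox factors and the potassium channels. For the olfactory, vomeronasal and keratin-associated genes the medians of family and random lists were both 0, so this test cannot show that they are low. Hox genes had a median of 0 against 1 (adjusted permutation p 0.318). The promoter shares were not compared at matched gene length. The X chromosome had 1.30 peaks per protein-coding gene and the Y chromosome 0.0703, against 2.14 to 4.59 on the autosomes. The animals were male, with 1 copy of each, but the cause of the low values was not tested.

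Of 6 further lists, none passed the threshold in the main comparison. Immediate early and AP-1 genes had a median of 4 peaks against 2 (adjusted permutation p 0.0732), and circadian clock genes 5 against 3 (0.208). With the mean in place of the median both had an adjusted p of 0.0252, and against all protein-coding genes 0.00720 and 0.0408. Oligodendrocyte and Schwann cell genes had 4 against 2 (0.208), T and B lymphocyte genes 4 against 2 (0.210) and voltage-gated ion channels 9 against 6 (0.251), or 9 against 2 without length matching (0.00120). Neuronal genes had 3 against 3 (1).

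Cluster 5 held 9.01 times as large a share of library 1 as of library 2. A difference in depth is argued against as the whole cause: in 10 bands of depth with equal numbers of nuclei the median fold was 6.88 (1.92 to 10.2), above the bound of 3 set before the test. Depth still varies within the outer bands; in band 5, from 235741 to 289235 counts, the fold was 6.49. Depth may still account for part of it: with nuclei thinned to 1 total and clustered anew, the largest fold fell to 3.04, though in another set of clusters (adjusted Rand index 0.404). A shift of AP-1 motifs throughout library 1 may contribute: within the other clusters the median log2 ratio of the 3 defining motifs was 0.0237, with values from -0.05 to 0.12, so the test does not decide. A difference between the animals also stays open, since with 2 libraries the animal and its library cannot be told apart.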
